A study of Helicoverpa armigera with 48 samples.

How the data were processed

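Agilent 2-colour arrays were hybridised with gut RNA of Helicoverpa armigera larvae in a loop design over 6 diets. Each diet had 4 pools of 10 fifth-instar larvae reared at 26 °C, and 500 ng of total RNA was labelled per sample with spike-in RNA added, per the labels' protocols. The submitters' processing notes name Agilent Feature Extraction 9.1. The authors deposited one linear intensity per feature and channel. Which background correction and dye normalization were applied before deposit, and whether columns were rescaled, is not given in the sources used here. The table held 43863 features, of which 43803 were probes and 60 control features, in 48 columns. Column medians of 41.7 to 92.9 differed by more than the limit set beforehand for using the values as deposited, so the scale was treated as not common. No pair of columns held identical values, and at most 1 probe had the highest value of a column, so no flat upper limit was seen. Of the 10 spike-in features, 3 were brighter in Cy5 and 4 brighter in Cy3 on all 24 arrays.

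Intensities were taken to log2 and quantile normalized between the 48 columns (limma 3.58.1, R 4.3.3). The Cy3 and Cy5 values of a pool were averaged, so that a pool counts as 1 replicate, with 4 per diet, and dye effects cancel. One linear model with a mean per diet was fitted to the 24 pools with limma's lmFit and eBayes, and each comparison was a contrast of it. P-values were adjusted by the Benjamini-Hochberg method over the 43803 probes, with a threshold of 0.05, and no probe was filtered. Data were simulated over 43803 probes from each probe's mean over all pools and its fitted spread, with 50 probes changed at each size. There the plants versus artificial diets contrast recovered 40% of probes changed by 0.5 on the log2 scale, 72% of those changed by 1 and 94% of those changed by 2, with 5 false calls. For the pinto bean versus wheat contrast these were 18%, 44% and 90%, with 13 false calls. Far more probes were called in the real data, so these rates and numbers of false calls do not carry over to the counts below.

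A probe was taken as above background in a column where its intensity exceeded 2 times the median of 26 negative control features. Where all channels of the dimmer side were at or below that limit, the change is a bound, written as at least N-fold: the mean of the brighter side against the dimmer side with each value raised to the normalized limit. Elsewhere the fitted log2 difference is given with the number of channels above background where some were not. Where chickpea fruit was raised on its bean pod arrays only, the bound takes chickpea fruit from its other arrays. Values at background have no order, so the named probes are not a ranking. The rule for naming, fixed before the data were examined, was the 2 probe identifiers with the largest change each way in each comparison, because no names are paired with the probes. None of the 43803 identifiers matched the RefSeq gene table of assembly ASM3070526v1. The gene lists and cell type markers fixed beforehand therefore could not be matched, and neither those lists nor camera or fry tests were run.

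The labels number the replicates 1 to 4 in every diet, and a number marks a loop of arrays. Deviations of same-numbered pools of different diets had a median correlation of 0.0582 (60 pairs, -0.508 to 0.393), and 27 of the 60 were above 0.1, so the numbers were not taken to pair the pools. The median was 0.14 for the 24 pairs that shared an array and -0.0139 for the 36 that shared none. The main model treats all pools as independent. Nothing in the labels says that the pools came from separate rearing batches. Alternatives fixed before the data were examined were columns as deposited or median centred, the dimmest 25% of probes left out, a replicate block, within-array differences with the replicate block, each dye alone, only the diets compared, and each pool left out in turn. Those added after the data were seen were columns centred on probes above background or on the spike-ins, channels rejoined across mismatched pools, 4 mismatched pools left out, probes measured on 1 array set left out, and cotton fruit left out. Correlations of fold changes between plants with shared or split controls were set beside 100 simulations in which the artificial diet pools were drawn around their own diet means and the plant pools around the mean of both.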

Results

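Gut RNA of fifth-instar larvae of the cotton bollworm, Helicoverpa armigera, a moth whose larvae feed on many crops, was measured on 2-colour arrays after feeding on 6 diets. The diets were an artificial diet made with pinto bean, an artificial wheat-based diet, cotton fruit, tobacco flower buds, bean pods and chickpea fruit. Each diet had 4 pools of 10 larvae, and each pool was hybridised once in Cy3 and once in Cy5, which gave 48 channels on 24 arrays. The 6 diets formed 4 closed loops of 6 arrays, in which the neighbours of bean pod were tobacco bud and chickpea fruit and the neighbours of cotton fruit were chickpea fruit and the pinto bean diet. The values covered 43803 probes. Column medians of the deposited intensities ran from 41.7 to 92.9, and 57.8% to 74.2% of the probes of a column lay above its background limit, set at 2 times the median of the negative control features. All columns held 20443 probes above the limit, and 5510 probes were above it in none. The files used here pair no gene names with the probes, so results are given for diets, for sets of probes and for a few probe identifiers. The 44 results for named probes concern 29 distinct probes. In 36 of the 44, every pool of one side lay beyond every pool of the other, and in 8 the ranges overlapped. The probes were named for their large changes in these same pools, which favours such separation. These counts therefore do not describe the called probes at large. The number of arrays limits the precision, and p-values measure only the spread between these pools.

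Profiles of tobacco bud and bean pod guts were as alike as those of the closest other pairs of diets. Over 28865 probes whose mean lay above background, the correlation across probes between pools of tobacco bud and bean pod averaged 0.946 (16 pairs of pools), 0.945 for cotton fruit and chickpea fruit, 0.944 for the wheat diet with either of these, and 0.943 for the pinto bean and wheat diets. Other pairs with tobacco bud or bean pod were lower, between 0.884 for cotton fruit and bean pod and 0.924 for tobacco bud and the pinto bean diet. Pools of one diet correlated at 0.964 to 0.983 on average, which is above each between-diet average. The first principal component held 33.8% of the variance and set tobacco bud and bean pod apart from the other 4 diets. The second held 18.3%, and along it pools of one diet were also apart, with wheat diet pools between -43.3 and 76.0 and cotton fruit pools between -78.3 and 29.1. The probes are not independent replicates, so these correlations describe profiles and carry no test.

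**Figure D1:**
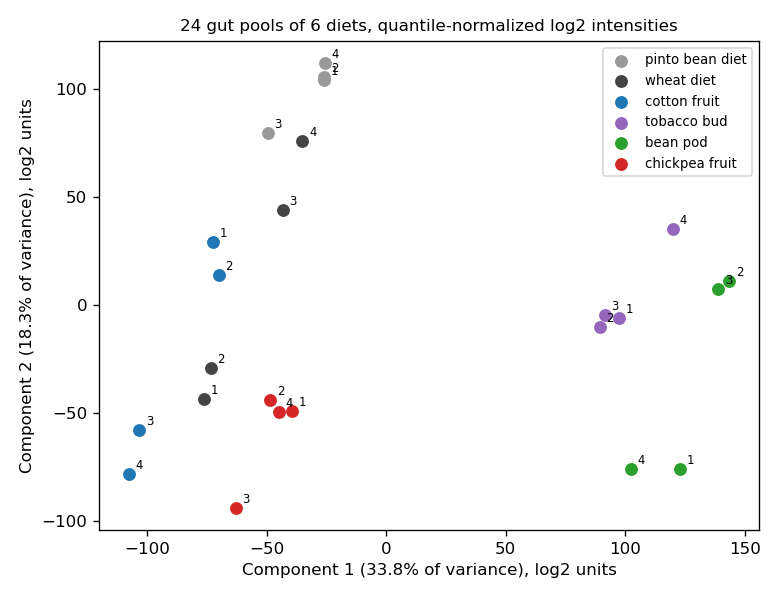
Principal components 1 (horizontal) and 2 (vertical) of the 24 pools, in log2 units, over probes whose mean lay above background. Each point is 1 pool, coloured by diet and marked with its replicate number, and the 8 tobacco bud and bean pod pools lie at the right, from 89.2 to 143 on component 1.

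**Figure D2:**
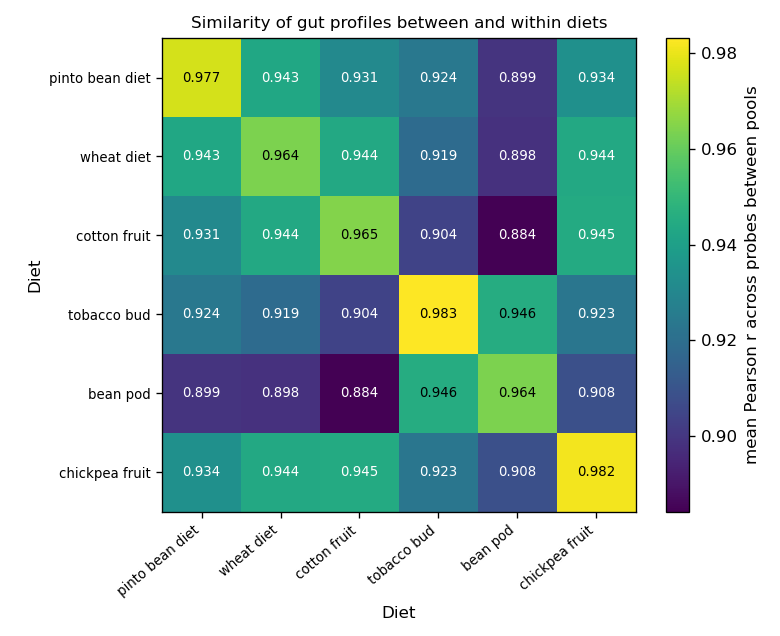
Mean Pearson correlation across 28865 probes between pools of each pair of diets, with both axes listing the 6 diets and the diagonal giving pairs of pools within a diet. The tobacco bud and bean pod cell reads 0.946 and the cotton fruit and bean pod cell 0.884.

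Some signals of the channels moved with diets or pools. The 10 features for the spike-in RNA, relative to the 75th percentile of the probes of the same column, read 1.15 ± 0.15 on the log2 scale in cotton fruit pools (SD, n = 4) and -0.23 ± 0.25 in the 20 other pools. Among the latter, the pinto bean diet read 0.185 ± 0.134 and the other 4 diets -0.47 to -0.262 on average, and each pinto bean diet pool, the lowest at 0.0103, lay above each pool of those 4 diets, the highest at -0.144. The cotton fruit difference from the 20 pools, 1.38 on the log2 scale or 2.60-fold, had an exact two-sided permutation p of 9.41e-05, the smallest that 10626 splits of the pools can give, and cotton fruit was singled out after the values were seen. Separately, after removal of diet and dye means, the Cy3 channel of 20 of the 24 pools correlated best with its own Cy5 channel, at r of 0.484 to 0.912 across 20443 probes. Pinto bean diet replicates 1 and 4 had r of -0.14 and -0.11 with their own second channel and 0.684 and 0.605 with each other's. Tobacco bud replicates 2 and 3 had -0.03 and -0.05 with their own and 0.795 and 0.604 with each other's. In addition, some probes of a pool were bright only on the array that the pool shared with a brighter neighbour: Har_00201988 read 2.51 ± 0.03 (SD, n = 4) in chickpea fruit on the arrays shared with cotton fruit and 11.11 ± 0.48 on those shared with bean pod, where bean pod read 18.13 ± 0.20. Diet means of such pools mix both kinds of channel. A wider set of 1902 probes was above background in all 4 channels of one array set and in none of the other in at least 1 diet. For 1852 of them these were Cy5 channels, and the neighbour had a log2 mean of 10 or more for only 43 of the 1902.

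**Figure D3:**
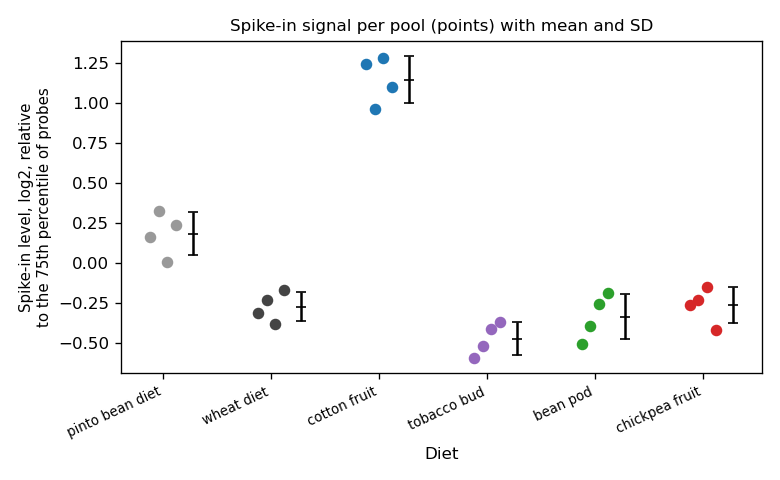
Spike-in level of each pool (points) on the log2 scale, relative to the 75th percentile of the probes, with the mean and SD of the 4 pools of each diet (bars). The lowest cotton fruit pool reads 0.963 and the highest pool of the other diets 0.326.

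In limma's moderated F test over the 6 diets, 25329 of 43803 probes passed an adjusted p of 0.05, and 20032 did with the 4 pools with mismatched channels left out. The median probe above background had 63.2% of its variance between diets. This is a raw share of the sum of squares. Part of it would arise by chance among 6 diets of 4 pools, and no baseline was computed. Among the probes that passed, cotton fruit had the highest diet mean for 6068, chickpea fruit for 4540, the pinto bean diet for 4211, bean pod for 3880, tobacco bud for 3874 and the wheat diet for 2756. Bean pod exceeded the next diet by at least 1 log2 unit for 756 probes, and the wheat diet for 147.

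Plant-fed guts were first compared with guts from the artificial diets, which serve as controls here. Of the probes, 5668 were higher and 6111 lower on the plants, 11779 in all, and 1469 and 1435 of these changed at least 2-fold. Har_00201988 had a log2 mean of 17.73 ± 0.04 in bean pod and 12.02 ± 1.07 in tobacco bud (SD, n = 4), but 2.50 ± 0.02 in cotton fruit and 2.52 ± 0.04 in the pinto bean diet. Its difference of 6.46 (SE 0.26, limma adjusted p = 7.08e-13) is therefore an average of unlike plants. The 6.48 of Har_00185667 (SE 0.32, adjusted p = 2.41e-11) has the same form, and both were above background in 3 of the 16 artificial diet channels. With the array and replicate block, which uses differences within arrays, they were 5.00 and 4.51, in Cy3 alone 4.57 and 4.65 and in Cy5 alone 8.35 and 8.31. Har_00041442 fell by 5.75 (SE 0.42, adjusted p = 8.06e-09) and Har_00053805 fell by 5.63 (SE 0.38, adjusted p = 1.82e-09), and both were above background in 19 of the 32 plant channels. The division into higher and lower depended on the scaling: with columns median centred, 4197 probes were higher and 15533 lower, as deposited 6576 and 3536, and with columns centred on the spike-ins 3875 and 14726. In Cy3 alone it was 5163 and 5159. Leaving out the 4 pools with mismatched channels gave 7513 calls.

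Cotton fruit raised 5562 probes and lowered 4056 against the artificial diets, with 1410 and 1694 of them changed at least 2-fold. Har_00055152 was 6.04 higher on the log2 scale (SE 0.42, adjusted p = 2.19e-08), at 14.35 ± 0.43 (SD, n = 4) in cotton fruit and 8.31 ± 2.07 in the artificial diets (n = 8), where 15 of 16 channels were above background. Har_00000073 was 5.59 higher (SE 0.37, adjusted p = 2.06e-08) and was above background in all 16 channels of the artificial diets, and the difference was 4.54 with the array and replicate block. Har_00091246 was at or below background in all 8 cotton fruit channels and was at least 67.9-fold lower there (adjusted p = 1.51e-08). Har_00000493 fell by 7.63 (SE 0.55, adjusted p = 2.42e-08) and was above background in 3 of the 8 cotton fruit channels. The same cotton fruit pools carried the raised spike-in signal. Without cotton fruit replicate 4 the count was 6344. The array and replicate block gave 3333 higher and 3330 lower, so the excess of higher probes was not kept. As deposited, 4516 were higher and 2405 lower, with columns median centred 3512 probes were higher and 3894 lower, with columns centred on probes above background 3511 and 4660, and with columns centred on the spike-ins 153 and 38578.

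Tobacco bud raised 5815 probes and lowered 6013, of which 2893 and 2646 changed at least 2-fold. In addition, 114 probes were above background in every tobacco bud channel and in no channel of the artificial diets, and 23 showed the opposite, all of them among the calls. Har_00002053 was 8.99 higher (SE 0.27, adjusted p = 4.64e-15), at 13.22 ± 0.36 (SD, n = 4) against 4.23 ± 1.59 (n = 8), and 4 of the 16 artificial diet channels were above background, with the wheat diet at 8.64 on the tobacco bud arrays and 2.71 on the others. Har_00070572 was 8.91 higher (SE 0.69, adjusted p = 8.34e-09), with 8 of 16 artificial diet channels above background and the wheat diet at 7.89 on the tobacco bud arrays and 3.15 on the others. With the array and replicate block these differences were 4.10 and 5.37, in Cy3 alone 7.24 and 7.93 and in Cy5 alone 10.75 and 9.89. Har_00231666 fell by 8.19 (SE 0.28, adjusted p = 3.18e-14) and was above background in 1 of 8 tobacco bud channels. Har_00102816 was at or below background in all 8 and at least 98.8-fold lower (adjusted p = 2.84e-09). As deposited, 6319 were higher and 4762 lower. Median centring gave 4715 higher and 15503 lower, centring on probes above background 5998 and 12821, and centring on the spike-ins 11535 and 2436. In Cy3 alone 4970 were higher and 4697 lower, and without tobacco bud replicate 4 these were 5587 and 5227. Without the 4 pools with mismatched channels, 2 of them tobacco bud pools, 5797 probes were called.

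Against the artificial diets, bean pod raised 5490 probes and lowered 6996, with 3084 and 2877 changed at least 2-fold. Har_00201988 was 14.42 higher (SE 0.36, adjusted p = 1.2e-16) and Har_00185667 was 14.08 higher (SE 0.46, adjusted p = 7.08e-15). Both were above background in 3 of 16 artificial diet channels, and in the wheat diet the Cy3 channels, which shared arrays with tobacco bud, carried most of the signal (5.61 ± 2.13 against 2.58 ± 0.12 in Cy5 for Har_00201988, SD, n = 4). With the array and replicate block the differences were 10.51 and 9.22. Among the called probes, 138 were above background in all bean pod channels and in no artificial diet channel, and 33 showed the opposite. Har_00231666 was at or below background in all 8 bean pod channels and at least 150.5-fold lower (adjusted p = 1.67e-14). Har_00072738 fell by 7.98 (SE 0.30, adjusted p = 6.27e-14), with 4 of 8 bean pod channels above background, at 5.76 on the chickpea fruit arrays and 2.56 on the tobacco bud arrays, and the difference was -6.25 with the array and replicate block, -6.41 in Cy3 alone and -9.54 in Cy5 alone. As deposited, 5976 probes were higher and 3740 lower, with columns median centred 4149 and 10409, and with columns centred on the spike-ins 7642 and 3261.

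Chickpea fruit raised 5388 probes and lowered 4818, of which 2083 and 1981 changed at least 2-fold. Only 7 probes were above background in all its channels and in none of the artificial diets. Har_00006884 was 6.69 higher (SE 2.03, adjusted p = 0.0212) and Har_00066943 was 6.60 higher (SE 1.90, adjusted p = 0.0154). Both had a wide spread in the artificial diets, 8.30 ± 3.96 and 7.94 ± 3.58 (SD, n = 8), where 11 of 16 channels were above background. The other plants spread widely too: Har_00006884 read 12.27 ± 4.35 in cotton fruit, 9.73 ± 3.48 in tobacco bud and 11.17 ± 2.94 in bean pod (SD, n = 4). Its SD in the pinto bean diet was 1.05 over pools, but 3.64 in Cy3 and 4.03 in Cy5. Replicates 1 and 4 of that diet had mismatched channels. The differences from the artificial diets were 4.51 and 4.32 with the array and replicate block and 5.49 and 5.48 without wheat diet replicate 4. Without wheat diet replicate 2 they were 7.42 and 7.22, and without wheat diet replicate 1 Har_00006884 was at 7.38. Har_00006884 no longer passed without chickpea fruit replicate 3 (adjusted p = 0.0644), in Cy3 alone (0.0584) or in Cy5 alone (0.0729), and Har_00066943 no longer passed in Cy5 alone (0.0691). Neither passed without the 4 pools with mismatched channels (0.0836 and 0.0695). Over all alternatives the adjusted p ran from 0.0115 to 0.0836 for Har_00006884 and from 0.00965 to 0.0695 for Har_00066943. Har_00041442 fell by 7.03 (SE 0.60, adjusted p = 1.76e-07) and Har_00009492 fell by 6.79 (SE 0.55, adjusted p = 8.91e-08), with 1 and 4 of 8 chickpea fruit channels above background. The block left Har_00009492 at -6.20, and with it 4348 probes were higher and 4544 lower. As deposited, 5326 probes were higher and 3136 lower, with columns median centred 4101 and 10801, with columns centred on probes above background 4802 and 6082, and with columns centred on the spike-ins 7096 and 2757.

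**Figure D4:**
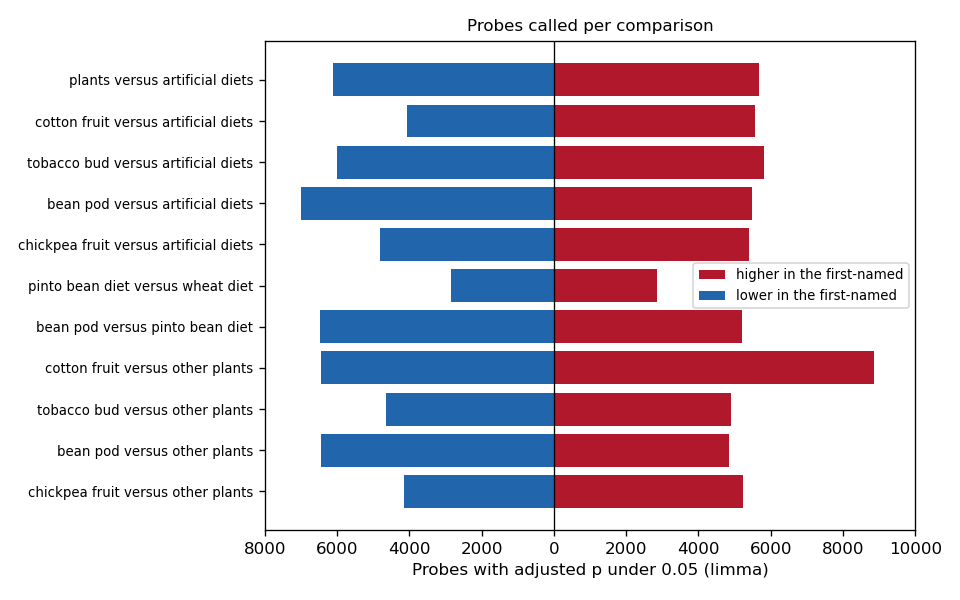
Number of probes with a limma adjusted p under 0.05 in each of the 11 pairwise comparisons, with probes higher in the first-named diet to the right of 0 and lower ones to the left. Cotton fruit versus other plants has the longest bar to the right, 8845 higher, with 6437 lower. Bean pod versus artificial diets has the longest bar to the left, 6996 lower.

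Tobacco bud and bean pod shared the most calls of any pair of plants, 2943 higher and 3826 lower than the artificial diets. Independent lists of these sizes would share 729 and 960. These 2 values leave out that the plants were compared with the same 8 artificial diet pools. With the controls split, so that one plant was set against the pinto bean diet and the other against the wheat diet, tobacco bud and bean pod shared 2029 or 2234 higher, where independent lists give 652 or 589, and 2462 or 2351 lower, against 894 or 765. Cotton fruit and bean pod shared 765 higher and 1510 lower with the same controls. With split controls they shared 467 or 356 higher, where independent lists give 684 or 389, and 882 or 675 lower, against 674 or 433. Independent lists are not the value for unchanged plants with split controls: in the simulations these shared a median of 0 higher calls for this pair, where independent lists gave 3.98 or 4.02. In all 4 plants 239 probes were higher and 657 lower against the shared controls. Independent lists would give 11 and 10, and the highest value in the simulations of unchanged plants was 0 in both directions. Unchanged plants give few calls by design, so that value could hardly have come out otherwise. It does not show how many of the 239 and 657 come from the shared artificial diet pools. Fold changes of tobacco bud and bean pod correlated across probes at 0.712, with a covariance of 0.645 against 0.0309 in the simulations, whose correlation was 0.333. With the controls split the correlation was 0.513 and 0.478 and the covariance 0.527 and 0.501, while simulated unchanged plants, which lie between the 2 artificial diets, gave -0.515 and -0.131 in both. From channels of the same arrays it was 0.67, and from channels on different arrays 0.609. For bean pod and chickpea fruit, which also share arrays, it was 0.395 on the same arrays and 0.152 on different ones, but tobacco bud and chickpea fruit, which share none, also had 0.303 and 0.133 in the 2 combinations of dyes. Cotton fruit and tobacco bud had a correlation of 0.0764, where simulated unchanged plants gave 0.334, but a covariance of 0.0461 against 0.031. With the controls split their correlation was -0.176 and -0.0427 against -0.514 in the simulations, and their covariance -0.142 and -0.0282 against -0.131. Of 3453 probes called in both, 1230 had opposite directions.

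The pinto bean and wheat diets differed in 5724 probes, 2865 higher and 2859 lower in the pinto bean diet, of which 1851 and 1066 changed at least 2-fold. Har_00022727 was at least 72.7-fold higher (adjusted p = 5.02e-09), at 10.03 ± 0.62 (SD, n = 4) against values at or below background in all 8 wheat diet channels. Har_00090412 was 7.29 higher (SE 0.39, adjusted p = 1.07e-09), with 2 of 8 wheat diet channels above background, or 8.19 in Cy3 alone and 6.39 in Cy5 alone. Har_00024300 fell by 6.06 (SE 0.60, adjusted p = 1.37e-06) and Har_00053947 fell by 5.64 (SE 0.94, adjusted p = 0.000574), with all 8 and 4 of 8 pinto bean diet channels above background. The array and replicate block gave -5.43 and -4.97, and Har_00053947 was at -4.83 without wheat diet replicate 1 and at -6.38 without wheat diet replicate 3, -4.745 in Cy3 alone and -6.53 in Cy5 alone. In Cy3 alone 5152 were higher and 5809 lower. The count rested on single pools: it was 3770, 3674 and 3165 without pinto bean diet replicates 1, 2 and 4, 7690 without pinto bean diet replicate 3, and 3377 and 3275 without wheat diet replicates 1 and 2. It was 1166 without the pools with mismatched channels. As deposited, 2429 were higher and 1274 lower, with columns median centred 3171 and 1532, and with columns centred on the spike-ins 1309 and 13513.

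Fresh bean pod and the diet made with pinto bean, both bean foods, differed in 11682 probes, 5209 higher and 6473 lower in bean pod. At least a 2-fold change was seen for 2967 and 3514 of them. Probes above background in every channel of one diet and none of the other numbered 257 for bean pod, 255 of them among the calls, and 51 for the pinto bean diet. Har_00201988 was at least 11400-fold higher (adjusted p = 7.92e-16) and Har_00185667 at least 9628-fold higher (adjusted p = 3.93e-14), with all 8 pinto bean diet channels at or below background. The array and replicate block, which sets no limit at background, gave fitted log2 differences of only 10.03 and 8.86. Har_00231666 was at least 178.1-fold lower in bean pod (adjusted p = 1.59e-13) and Har_00053805 at least 146.4-fold lower (adjusted p = 4.36e-09). The fitted difference of Har_00053805 was -8.19, -9.07 without pinto bean diet replicate 3, -7.59 with the array and replicate block and -7.37 without the 4 pools with mismatched channels. As deposited, 5322 were higher and 3893 lower, with columns median centred 3880 and 15070, and with columns centred on the spike-ins 11468 and 2356. Without the 4 pools with mismatched channels, 7728 were called.

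Each plant was then set against the mean of the other 3, which tests whether the response differed between plants. Cotton fruit had the most calls, with 8845 probes higher and 6437 lower. The comparators were unlike: tobacco bud and bean pod, which had similar profiles, were each set against a mean that held the other. Changes of at least 8-fold numbered 126 higher and 380 lower for cotton fruit, and 480 and 62 for bean pod. Against the artificial diets, cotton fruit had the fewest calls of the plants, 9618, and bean pod the most, 12486. Har_00121190 was at least 68.5-fold higher in cotton fruit (adjusted p = 2e-08), at 9.74 ± 1.31 (SD, n = 4), with all 24 channels of the other plants at or below background. It was not particular to cotton fruit, as the pinto bean diet read 8.39 ± 0.73 and the wheat diet 3.89 ± 1.92. Har_00075700 was 6.56 higher (SE 0.51, adjusted p = 1.31e-08). Har_00185667 and Har_00002053 were lower (adjusted p = 2.73e-12 and 8.8e-16), with all 8 cotton fruit channels at or below background. Their chickpea fruit values were raised on the bean pod arrays, at 12.06 and 11.85 against 2.90 and 3.65 on the cotton fruit arrays. With chickpea fruit taken from the latter, they were at least 101-fold and at least 124-fold lower than the mean of the other plants. Chickpea fruit itself lay under the mean limit of 3.93 there, so these folds rest on tobacco bud and bean pod. The adjusted p-values come from the fit that includes the raised chickpea fruit channels. The array and replicate block gave fitted differences of only -4.35 and -3.61. Median centring gave 12330 higher and 5477 lower, centring on probes above background 6716 and 7066, and centring on the spike-ins 337 and 39830.

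Tobacco bud differed from the other plants in 4904 probes higher and 4640 lower. Har_00106697 was 7.76 higher (SE 0.67, adjusted p = 7.99e-08) and Har_00200117 was 6.44 higher (SE 0.24, adjusted p = 3.03e-13), each with 10 of 24 channels of the other plants above background. Bean pod was at 7.85 ± 2.53 for Har_00106697 and at 10.29 ± 0.62 for Har_00200117 (SD, n = 4), near the 11.80 ± 0.40 of tobacco bud, while cotton fruit and chickpea fruit were at 2.73 and 3.06 for Har_00200117. With the array and replicate block the differences were 4.60 and 5.62, and that of Har_00106697 was 8.37 in Cy3 alone and 7.15 in Cy5 alone. Har_00231666 fell by 6.18 (SE 0.27, adjusted p = 3.58e-12) and Har_00087707 fell by 5.89 (SE 0.29, adjusted p = 2.81e-11), with 1 and 4 of 8 tobacco bud channels above background. The 4 channels of Har_00087707 were those on the wheat diet arrays, at 4.30 against 3.11 on the bean pod arrays. Without the 4 pools with mismatched channels, 4712 probes were called. Median centring gave 4284 higher and 4621 lower, and centring on the spike-ins 27203 higher and 1074 lower.

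Bean pod was higher than the other plants for 4846 probes and lower for 6435. Har_00201988 was 10.62 higher (SE 0.34, adjusted p = 1.22e-14) and Har_00210099 was 10.23 higher (SE 0.39, adjusted p = 1.68e-13), with 12 of 24 channels of the other plants above background. Their chickpea fruit means include the raised channels on the bean pod arrays, and the array and replicate block gave 7.34 and 6.62, Cy3 alone 12.66 and 11.98 and Cy5 alone 8.59 and 8.48. Har_00231666 was at least 37.5-fold lower than the mean of the other plants (adjusted p = 1.06e-12). Har_00072738 fell by 5.97 (SE 0.28, adjusted p = 4.13e-12), with 4 of 8 bean pod channels above background. The difference of Har_00072738 was -4.74 with the block, -3.79 in Cy3 alone and -8.15 in Cy5 alone. For both, bean pod was below cotton fruit and chickpea fruit only: tobacco bud read 2.76 against 2.74 in bean pod for Har_00231666 and 4.91 against 4.16 for Har_00072738, with no pool of either diet above background in both channels. As deposited, 4545 were higher and 3929 lower, with columns centred on probes above background 5527 and 4684, and on the spike-ins 20017 and 1497.

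Chickpea fruit was higher than the other plants for 5238 probes and lower for 4152. Har_00231666 was 6.55 higher (SE 0.27, adjusted p = 1.39e-12), at 12.30 ± 0.35 (SD, n = 4) in chickpea fruit, 11.77 ± 0.76 in cotton fruit, 2.76 ± 0.10 in tobacco bud and 2.74 ± 0.30 in bean pod. Only 9 of 24 channels of the other plants were above background, so the size is set in part by values at background. Har_00177618 was 5.98 higher (SE 0.19, adjusted p = 2.47e-14), with 12 of 24 channels of the other plants above background and means of 9.88 in cotton fruit, 3.75 in tobacco bud and 3.18 in bean pod. Har_00117485 fell by 7.05 (SE 0.68, adjusted p = 3.74e-07) and Har_00065118 fell by 5.89 (SE 0.72, adjusted p = 7.11e-06), each with 4 of 8 chickpea fruit channels above background. For Har_00117485 these were the channels on the bean pod arrays, at 4.40 against 2.73 on the cotton fruit arrays, and the difference was -7.98 in Cy3 alone and -6.12 in Cy5 alone. As deposited, 3605 were higher and 3720 lower. Centring on the spike-ins gave 13992 higher and 1827 lower.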

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

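The tests of array brightness, cross-hybridisation, labelled RNA share, whole-array exchange, noisy hybridisation, carry-over, mixed RNA and dye bias were chosen after the result was seen.

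The spike-in signal, relative to the 75th percentile of the probes, was 1.38 higher on the log2 scale in cotton fruit pools than in the other diets. Of those, the pinto bean diet was at 0.185 and the rest at -0.262 or lower. Spike-in values are used in the comparisons of diets only where columns are centred on them. A smaller share of labelled gut RNA, if present, would still bear on all cotton fruit comparisons, because quantile normalization gives every column the same distribution. Brightness that lifts a whole channel cancels in this relative level, so it was not tested. For bright arrays or scans, the other pool on each cotton fruit array was compared with its own second channel. It exceeded that channel by 0.262 (SE 0.0803, 8 channels), below the 0.689 that was set as the bound. This argues only against an array effect on the spike-in features as the source of most of the rise. A smaller part of the rise may follow the array. Cross-hybridisation of cotton or gut RNA is argued against by all 10 spike-in features rising, the lowest by 1.26 and the highest by 1.66. A larger dose of spike-in, or a smaller share of labelled gut RNA in the same total RNA, may account for it. These cannot be told apart: the 75th percentile of the intensities was 0.0566 higher in cotton fruit columns (SE 0.0579), but the channels of an array had nearly one level (r = 0.995 over arrays), which would hide a lower share, and a biological difference in messenger RNA content was not tested.

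In 4 pools the Cy3 and Cy5 channels did not match each other but matched those of another pool of the same diet. Over 8422 probes that had not been used to find this, the lowest crossed correlation was 0.382, against -0.225 to -0.0752 for the labelled pairs of these 4 pools and at least 0.186 for the other 20. This is consistent with labels exchanged in 1 dye between pinto bean diet replicates 1 and 4 and between tobacco bud replicates 2 and 3. Exchange of whole arrays is argued against by the other 8 pools on those arrays, whose own correlation was at least 0.781, and noisy hybridisation by the lowest crossed correlation of 0.604 over the first set of probes. Exchanged labels within a diet leave diet means as they are, but each value of these 4 pools would then average channels of different pools. That can make the spread between pools too small, and with it the SDs, SEs and p-values given above. With channels rejoined the F test gave 24926 calls, against 25329 as labelled. No biological explanation was tested.

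Some probes were raised in a pool on the array that it shared with a brighter pool. Among probes at or below background in a diet's channels on its other arrays, 60.8% of 97 were above background in at least 3 of 4 channels where the partner's log2 mean was 10 to 13, against 3.08% of 136827 where it was under 4, which is consistent with signal carried over between the channels of an array. Within Cy3 these were 48.1% and 0.205%, and within Cy5 65.7% and 5.63%. A probe counts once in each diet and array set in which it qualified, of which there were 12, so it can count several times. Dye bias is argued against at 31 chickpea fruit probes raised on the bean pod arrays, with a bean pod mean over 13, where bean pod itself differed by -0.103 between Cy5 and Cy3. Mixing of RNA cannot be told apart from it by the bound that was set, because the median chickpea fruit value of 4.10 on arrays without bean pod lay just above the limit of 3.93 (10.76 on arrays with it), and mixing after labelling would look like carry-over; no biological explanation was tested.

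Tests of the difference between plants gave 15282 probes for cotton fruit against the other plants, 9544 for tobacco bud, 11281 for bean pod and 9390 for chickpea fruit. Single pools stood apart in 4 of 63 groups tested, and chance flags about 1 in 20. For Har_00070572, tobacco bud replicate 4 read 13.10 against 13.82 to 13.86 (gap 0.947 of the range). For Har_00106697, the same pool read 11.13 against 13.17 to 13.34 (0.925). For Har_00090412, wheat diet replicate 4 read 3.49 against 2.88 to 2.96 (0.858), all near background. For Har_00053805, pinto bean diet replicate 3 read 8.26 against 11.66 to 11.90 (0.934).

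Each of the 12 counts was set beside other splits of the same pools, with a level of 0.05. Nearly all of these splits mix diets within a group, which raises the spread within groups. They therefore show whether pools group by diet, and cannot exclude chance for the count of a single comparison. Among the splits drawn, the real split gave the most calls, 1 of 100 splits, for the F test (25329, highest other 955), plants versus artificial diets (11779, 6433), cotton fruit (9618, 7163), tobacco bud (11828, 9897), bean pod (12486, 9011) and chickpea fruit (10206, 9631) against the artificial diets, and cotton fruit (15282, 11281), bean pod (11281, 7802) and chickpea fruit (9390, 8778) against the other plants. It was 1 of 35 splits for pinto bean versus wheat diet (5724, 4298) and for bean pod versus pinto bean diet (11682, 178). For tobacco bud against the other plants, 3 of 100 splits gave as many as 9544, the others being the splits that set cotton fruit (15282) or bean pod (11281) apart. For bean pod and chickpea fruit against the other plants, no split that set another plant apart was drawn. The split with cotton fruit apart gives 15282, more than the real split of either. High counts in other splits reflect structure among the pools: the split of 9897 set the pinto bean diet apart from the wheat diet and tobacco bud, and those of 7163, 9011, 9631 and 4298 set pinto bean diet replicates 1, 2 and 4 with 1 wheat diet pool apart.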

How the results depend on the processing

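The tests with spike-in centring, centring on probes above background, rejoined channels, mismatched pools, cotton fruit or probes on 1 array set left out were chosen after seeing the data. The totals of all 12 counts stayed within 1.5 times their value with the dimmest 25% left out, with the array and replicate block, with channels rejoined (5238 for pinto bean versus wheat diet, 24926 for the F test) and with probes measured on 1 array set left out. Within these totals, the array and replicate block turned 5562 higher and 4056 lower for cotton fruit versus artificial diets into 3333 and 3330, and 5388 and 4818 for chickpea fruit into 4348 and 4544. The replicate block gave 25733 for the F test, 11981 for plants versus artificial diets and 5555 for pinto bean versus wheat diet, and changed no call count by over 1.5 times. Other values, whose cause was not tested, follow. Median centring gave 19730 for plants versus artificial diets, 20218 for tobacco bud versus artificial diets and 18950 for bean pod versus pinto bean diet, and moved the median of all probes to -0.23, -0.32 and -0.39. Centring on probes above background gave 18819 for tobacco bud. Spike-in centring gave 41739 for the F test, 18601 for plants and 38731 for cotton fruit versus artificial diets, 14822 for pinto bean versus wheat diet, and 40167, 28277, 21514 and 15819 for cotton fruit, tobacco bud, bean pod and chickpea fruit versus other plants. It moved the median of all probes to -1.26 for cotton fruit versus artificial diets. Pinto bean versus wheat diet gave 3703 as deposited, 10961 in Cy3 alone, 9854 in Cy5 alone and 3349 with only these diets in the fit. With fewer pools, those with mismatched channels left out, counts were 20032 for the F test, 7513 for plants and 5797 for tobacco bud versus artificial diets, 1166 for pinto bean versus wheat diet, 7728 for bean pod versus pinto bean diet and 4712 for tobacco bud versus other plants. Without cotton fruit the F test gave 22300 and plants versus artificial diets 13934.

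Leaving out 1 pool gave 3165 to 7690 for pinto bean versus wheat diet and 6344 to 10280 for cotton fruit versus artificial diets, and within 1.5 times the count elsewhere. The named probes were chosen for the largest changes in these same pools, which favours stable results, so they do not stand for other calls. Of 1121 values of the named probes, 1115 kept direction and threshold, 6 kept direction only and 0 reversed. Sizes moved more: with the array and replicate block 23 of 44 were over 1.5 times smaller on the fold scale and 0 larger, such as Har_00002053 in tobacco bud (8.99 to 4.10 on the log2 scale) and Har_00201988 in bean pod (14.42 to 10.51). In Cy3 alone 10 were smaller and 6 larger, in Cy5 alone 6 and 9, and with spike-in centring 7 and 7.

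Shared calls with the controls split, the first plant against pinto bean diet and then against wheat diet, were for cotton fruit and tobacco bud 547 and 457 higher, 772 and 652 lower, for cotton fruit and bean pod 467 and 356 higher, 882 and 675 lower, for cotton fruit and chickpea fruit 892 and 636 higher, 907 and 715 lower, for tobacco bud and bean pod 2462 and 2351 lower, for tobacco bud and chickpea fruit 1228 and 1162 higher, 1274 and 1227 lower, and for bean pod and chickpea fruit 1114 and 870 higher, 1197 and 1274 lower. Independent lists would share 693 and 436 higher for cotton fruit and tobacco bud and 684 and 389 for cotton fruit and bean pod, and fewer than observed in all other cases; simulated unchanged plants share fewer than independent lists. Fewer pools per comparison enter these. Gene list alternatives were not run. Signal near background limits folds of dim probes.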

Other observations

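Both tests below were set before the result was seen, but the reading of the test of plant RNA was changed after it. Guts from the 2 artificial diets did not form 2 tight groups. On an axis on which the wheat diet mean of the other pools is 0 and the pinto bean diet mean is 1, pinto bean diet replicates 1, 2 and 4 lay at 1.03, 1.02 and 1.11 and replicate 3 at 0.513. Wheat diet replicates 1 and 2 lay at -0.152 and -0.103, and replicates 3 and 4 at 0.299 and 0.485. Bean pod and tobacco bud shared 76 of their 138 and 114 probes that were above background in all of their channels and in none of the artificial diets. Of the 138 bean pod probes, 2 were above background in all chickpea fruit channels and 0 in all cotton fruit channels.

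RNA of the eaten plant in the gut is a candidate explanation for these 138 and 114 probes, of which 6 on bean pod and 2 on tobacco bud were above background in no channel of any other diet. As RNA of 1 source, these probes would move together between the 4 pools, and the bound was 50% of their variance between pools. A common amount held 7.13% for bean pod (matched probes 0.807% to 15.2% in 100 sets) and 3.89% for tobacco bud (0.0425% to 12.4%). Both shares met the bound written beforehand as evidence against plant RNA. That reading was dropped after the values were seen, because pools with equal amounts of plant RNA would also give a low share, and both shares lay within the range of matched probes. Plant RNA therefore remains open and without evidence for it. Over the scalings of the columns the median difference ran from 4.64 to 5.02 for bean pod and from 3.27 to 3.78 for tobacco bud, so its size depended little on the scaling. This test could hardly have come out otherwise, because the probes were chosen from the same values by a limit within each column. Probe sequences, which would decide, were not used here.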
